A study of Mus musculus with 15 samples.

How the data were processed

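Carotid arteries of female mice were profiled on arrays 5 days after ligation of the left common carotid artery, in 4 groups: wildtype non-ligated (n = 4), wildtype ligated (n = 4), Has3-deficient non-ligated (n = 4) and Has3-deficient ligated (n = 3). Per the labels the mice were 21 to 22 weeks old and 100 ng of RNA was amplified. The labels do not say whether the samples come from separate animals, so p-values measure the spread between these samples.

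The deposited table holds log2 values of 33793 probe sets in 15 arrays, each relative to the median of its own probe set over the arrays. Levels are therefore lost, but for a rough trace, and differences between arrays are kept. The trace is the size of the steps between stored numbers, which for 1951 genes is that of numbers in the highest range before centring; these are called bright genes. It does not rank genes by level, as the planned filter would need. Array medians lie within 0.017 of 0. The log base was read from the values. The normalization between arrays, the software and the annotation build are not given in the sources used here.

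Gene names came from the reference tables given with the data (gene table of assembly GRCm 38, patch 6). Of the probe sets 23521 carried 1 gene symbol, 1814 carried several and 8458 were unlisted; the last groups were tested as probe sets only. For 1082 genes with several probe sets the mean was used, giving 22180 genes. Probe sets did not always agree. Of 327 wildtype ligation calls with several probe sets, 34 had probe sets of opposite sign. In Has3-deficient arteries this held for 19 of 216. The plan, made before the data were examined, was to use the brightest probe set, a filter on dim genes and a variance trend as an alternative. Centring removed the levels that these need, so the mean was chosen after the table was seen.

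The 4 groups were fitted in 1 linear model with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation (11 residual and 2.69 prior degrees of freedom). The comparisons were ligation within each genotype, genotype within each artery state, and the difference of the ligation responses (interaction). A gene passed at a Benjamini-Hochberg adjusted p under 0.05 over all genes; calls "adjusted over the list alone" are adjusted over the members of a list. Ligation in wildtype and ligation in Has3-deficient arteries share no array, nor do genotype in ligated and genotype in non-ligated arteries; all other pairs of comparisons share arrays. The fit was tested on simulated data with 200 changed genes: of changes of 1 log2 unit 76.1% to 100% were recovered, depending on the comparison, and 4.2% to 8.2% of calls were false. In 20 simulations, run for genotype in ligated arteries alone, a list shifted by 0.3 log2 units was found 20 times, and 1 other list was called. Noise was drawn separately for each gene in all these simulations. They therefore do not test list calls at the preset correlation where the members of a list vary together.

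Before the data were examined 32 gene lists with 564 genes were fixed, of which 510 genes were measured; 4 were renamed to current symbols. The erythroid list had fewer than 5 measured genes and was left out, so 31 lists were tested with camera at a preset correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation, fry and exact permutation of list means over the splits of the arrays were run beside it.

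Genes were named by rule: the hyaluronan synthases, the 8 genes with the largest passing change in each direction, up to 4 passing members per list, and, where fewer than 5 genes passed, up to 5 with the lowest p. The 8 were taken among genes whose arrays did not overlap between the 2 groups compared. Predicted genes, microRNA and snoRNA genes, and immunoglobulin and T cell receptor segments were left out of the 8 and of the 5. Mir3108 was named after its value was seen. The alternatives were quantile normalization, a common median, array weights, only the 2 groups compared, a block for replicate number, camera with an estimated correlation, fry and leaving out each array in turn. Others were added after the data were seen: a robust prior, another choice of probe set, bright genes only, exact permutation of list means, leaving out the array highest in neuronal genes or the arrays with a list mean above 1 for neuronal or fat genes, and these means as covariates. No array was left out of the comparisons reported.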

Results

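Carotid arteries of wildtype and Has3-deficient mice were compared with and without ligation, 5 days after surgery. Has3 makes hyaluronan, a large sugar polymer of the matrix. The Has3 probe set did not pass as lower in the arrays labelled Has3-deficient: the change was 0.09 ± 0.14 log2 units (± standard error) in non-ligated arteries and -0.20 ± 0.16 in ligated ones. This probe set therefore does not check the genotype labels, and its position relative to the deleted part of the gene is not known here, so "Has3-deficient" below follows the labels.

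Ligation changed the wildtype artery widely. Genes of inflammation, of dividing cells, of matrix and of matrix-degrading enzymes rose, and genes of contractile smooth muscle fell. Of 22180 genes tested with limma, 6173 passed, 2925 higher and 3248 lower. More than 2-fold changes were seen for 809 of the higher and 359 of the lower genes. Of 31 gene lists 17 passed, 13 up and 4 down, and 4 of them held with an estimated correlation.

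Genes of inflammation were among those with the largest rises. Il1b, which encodes the cytokine interleukin 1 beta, rose by 5.63 ± 0.65 log2 units (49.4-fold, adjusted p = 1.55e-05). Saa3, an acute-phase protein, rose by 5.57 ± 0.27 (47.6-fold), the chemokine Ccl3 by 5.57 ± 0.46, and Clec4d and Clec4e, lectin receptors of myeloid cells, by 5.49 ± 0.33 and 5.35 ± 0.31. Acod1, an enzyme of activated macrophages, rose by 5.33 ± 0.44, Il1f9 by 5.17 ± 0.24 and Cxcl3 by 5.15 ± 0.29. Klk10 (-3.26 ± 0.33) and Ptprz1 (-2.84 ± 0.29) fell most among genes eligible under the naming rule. Hhip, a binder of hedgehog ligands (-2.83 ± 0.34), and Omd (-2.43 ± 0.20) followed. C7, a complement component, fell by 2.15, Abca8a by 2.00, Olfr224 by 1.99 and Synpo2, an actin-binding protein of muscle, by 1.89.

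Genes of the hyaluronan system rose in part. The synthase Has2 rose by 1.25 ± 0.18 log2 units (2.38-fold, adjusted p = 0.000126) and Has1 by 0.81 ± 0.21 (1.75-fold, adjusted p = 0.00928), while Has3 (0.13 ± 0.14) did not pass. The Has3 probe set did not pass as lower in arrays labelled Has3-deficient either, so this does not show that Has3 was unchanged. The call for Has1 held in 19 of 20 alternatives and that for Has2 in 20 of 20. Of 24 members of the list measured, 11 rose, 1 fell and 12 did not pass. Adjusted over the list alone, 12 rose and 1 fell. Tnfaip6, which modifies hyaluronan (3.02), its receptor Cd44 (2.53), Tlr2 (1.72) and Hmmr (1.41) rose most. The list had an adjusted p = 0.00195 at the preset correlation and an adjusted p = 0.0722 with an estimated correlation.

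**Figure D1:**
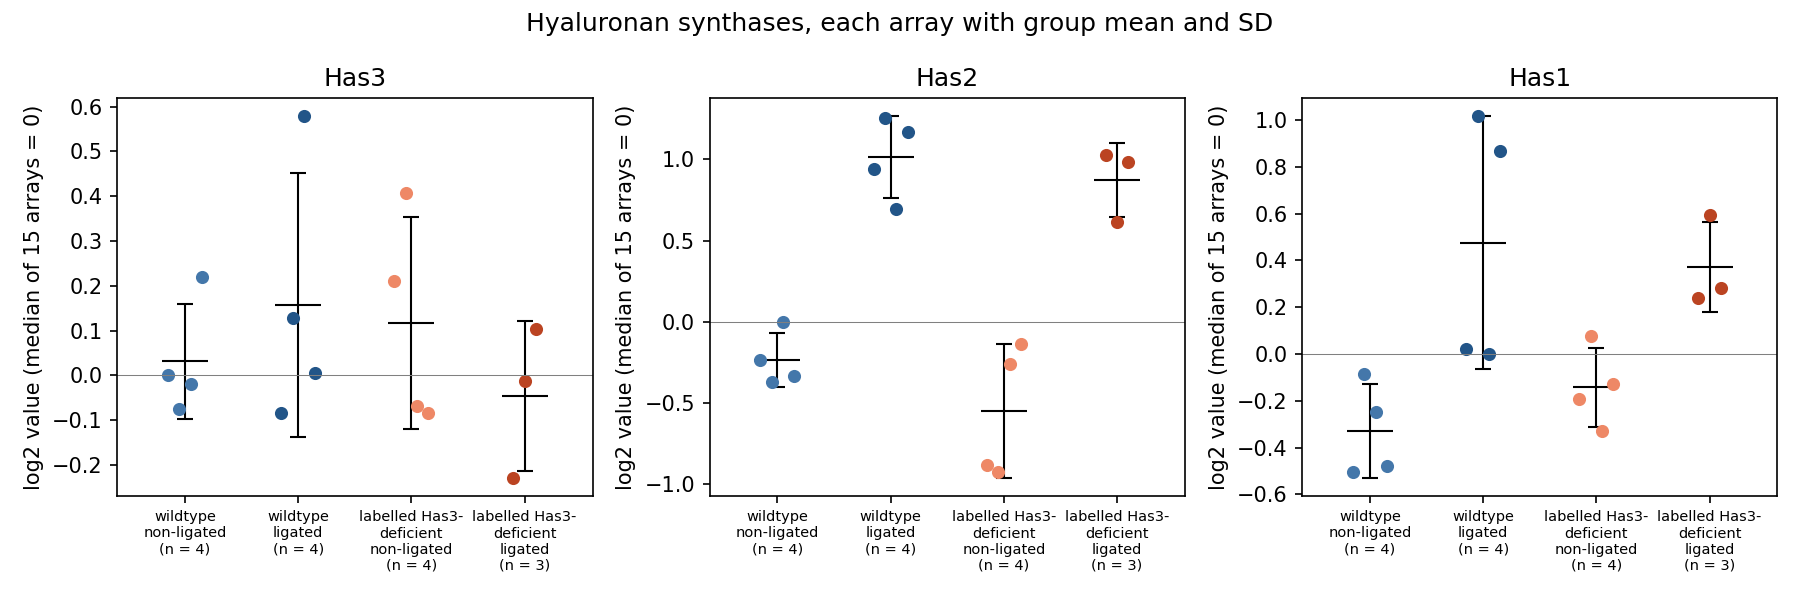
Has1, Has2 and Has3 in each of the 15 arrays, by group. Values are log2 units relative to the median of each probe set over all arrays, with group mean and standard deviation. Has2 rose with ligation in both genotypes (1.25 in wildtype, 1.43 in Has3-deficient arteries). Has3 passed in neither, and its probe set did not pass as lower in arrays labelled Has3-deficient.

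Genes of macrophages, neutrophils and their signals were among those that rose. Of 22 macrophage genes 21 rose over all genes and 21 adjusted over the list alone, among them Mpeg1 (4.21) and Cd14 (3.98); the list's mean change was 2.24, with an adjusted p = 0.0722 with an estimated correlation. Of 15 neutrophil genes 10 rose, also 10 adjusted over the list alone, such as Il1r2 (4.10) and S100a8 (4.06), adjusted p = 0.0725 with an estimated correlation. Of 25 chemokine, cytokine and adhesion genes 24 rose, also 24 adjusted over the list alone, with Cxcl2 at 4.61 and Tnf at 3.89, adjusted p = 0.0172 with an estimated correlation. Of 18 interferon response genes 12 rose and 6 did not pass, 13 rose and 1 fell adjusted over the list alone, with Oas2 at 1.90, adjusted p = 0.336 with an estimated correlation. Of 13 T and NK cell genes 6 rose, 9 adjusted over the list alone, with small changes such as Ncr1 (0.58), adjusted p = 0.261 with an estimated correlation. None of 11 B and plasma cell genes passed.

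Matrix and its enzymes rose. Of 19 genes of matrix and fibrillar collagen 15 rose, also 15 adjusted over the list alone, with Thbs1 (3.56), P4ha3, which modifies collagen (3.34), and Tnc (2.90); the list held with an adjusted p = 0.0172 with an estimated correlation. Of 21 matrix proteases and inhibitors 18 rose and 1 fell, the same numbers adjusted over the list alone, with Mmp12 (4.93), Adam8 (4.23) and Mmp13 (3.78), adjusted p = 0.0157 with an estimated correlation.

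Genes of cell division rose together. All 24 mitosis genes rose, and all 24 adjusted over the list alone, with Mki67 (2.45) and Top2a (2.08), adjusted p = 0.0378 with an estimated correlation. Of 23 DNA replication genes 20 rose and 1 fell, the same numbers adjusted over the list alone, by less on average (0.41), with Cdt1 at 0.89, adjusted p = 0.0725 with an estimated correlation.

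Genes of the contractile apparatus of smooth muscle fell. Of 21 members 19 fell and 2 did not pass, and 20 fell adjusted over the list alone, with Lmod1 (-1.53), Pdlim3 (-1.45) and Tpm2 (-1.33); the mean change was -0.999, with an adjusted p = 0.156 with an estimated correlation. Of 13 adventitial fibroblast genes 7 fell and 1 rose, 8 and 1 adjusted over the list alone, with Clec3b (-1.04) and Gsn (-0.98), adjusted p = 0.156 with an estimated correlation. Endothelial genes went both ways, 5 up (Emcn 1.50) and 6 down (Tek -1.45) of 15, and the list did not pass.

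Smaller groups moved too. Immediate early genes rose in 10 of 20 (11 adjusted over the list alone; Fos 1.76, adjusted p = 0.156 with an estimated correlation), hypoxia and glycolysis genes in 9 of 17, with 1 fallen (10 and 2 adjusted over the list alone; Egln3 1.69, adjusted p = 0.466 with an estimated correlation). Unfolded protein response genes rose in 7 of 15, also 7 adjusted over the list alone (Sdf2l1 0.82, adjusted p = 0.218 with an estimated correlation). The respiratory chain list was lower on average (-0.41), yet 1 of 21 members fell (Atp5c1 -0.28) and none adjusted over the list alone, adjusted p = 0.739 with an estimated correlation. Without wildtype non-ligated array 1 this list was at -0.17 and did not pass, and Atp5c1 did not pass without wildtype non-ligated array 1 (-0.21), 2 (-0.285) or 4 (-0.27), or ligated array 1 (-0.26), 2 (-0.25) or 4 (-0.26). White and brown fat genes fell in 6 of 15, 7 adjusted over the list alone (Retn -1.57, adjusted p = 0.466 with an estimated correlation), and their list means ran from -1.24 to 1.68 over single arrays.

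Lists of other cells and tissues did not pass as lists in wildtype: mast cell (2 of 8 rose, Hdc 4.41), lymphatic endothelial (2 rose, 1 fell; Pdpn 2.38), platelet (2 of 8 rose, Pf4 2.28), growth factors and receptors (7 rose, 3 fell; Hgf 1.81), cholesterol synthesis (3 of 14 fell; Insig1 -1.06) and circadian clock (2 of 14 fell; Nr1d1 -1.05). Neither did those of skeletal muscle (1 of 20 fell, Casq1 -1.40), Schwann cell (1 of 9 rose, Egr2 1.96), epithelium (1 of 13 rose, Cdh1 0.44), the neighbours of Has3 (2 rose and 8 fell of 22), neuron and chromaffin, and thyroid and parathyroid (no member passed in these last lists).

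Ligation in Has3-deficient arteries moved many of the same genes as in wildtype. Of 22180 genes 4055 passed with limma, 2262 higher and 1793 lower. Of the higher genes 1994 were also higher in wildtype (88.2%; 298.3 expected if independent), and of the lower ones 1448 were also lower (80.8%; 262.6 expected); 2 genes passed in opposite directions. Both comparisons use 1 shared estimate of each gene's spread, so part of the excess over the numbers expected if independent can come from that. Across all genes the changes of both genotypes correlated with r = 0.91 and a rank correlation of 0.714. The Has3-deficient ligated group has 3 arrays, 1 fewer than the others. With 1 wildtype ligated array left out, the wildtype count was 5470 to 5689, so group size alone does not account for the lower count. A lower count is not a tested difference, and the interaction, described below, passed for 0 genes. The standard deviation of the changes over all genes was 0.516 in wildtype and 0.479 in Has3-deficient arteries. The Has3-deficient count also varied with the array left out, as given below.

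Among genes eligible under the naming rule, Il1b (5.42 ± 0.70) and Stfa2l1, an inhibitor of cysteine proteases (5.17), rose most. Saa3 (5.05), Ccl3 (4.89), Clec4d (4.87), Clec4e (4.79), Acod1 (4.76) and Cxcl3 (4.58) followed. Of the eligible genes, Klk10 (-2.16), Hhip (-2.16), Stk32a (-1.87) and Inmt (-1.80) fell most. Abca8a (-1.73), Spock2 (-1.70), Kif1a, a motor protein of neurons (-1.66), and Akap6 (-1.59) followed. Without Has3-deficient ligated array 3, Stk32a (-1.78), Spock2 (-1.54) and Kif1a (-1.51) did not pass, and Stk32a did not without array 5 (-1.91) or 6 (-1.92) either. Has2 rose by 1.43 ± 0.20 (2.69-fold, adjusted p = 0.000138). Has1 did not pass (0.51 ± 0.23), nor did its difference from the wildtype response (-0.29 ± 0.31, adjusted p = 0.835).

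**Figure D2:**
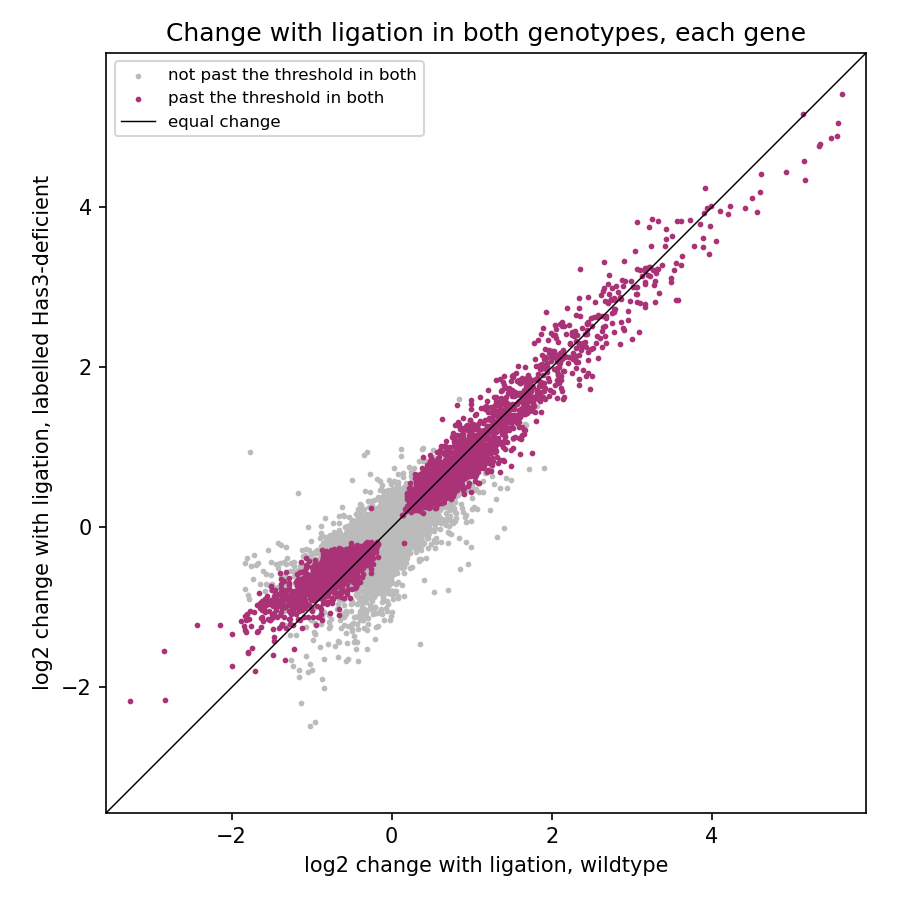
Change with ligation in wildtype and in Has3-deficient arteries, log2 units, for 22180 genes; r = 0.91. The changes share no array.

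Of 31 lists 14 passed, 12 up and 2 down, and 7 of them held with an estimated correlation. Hyaluronan genes rose in 8 of 24, 9 adjusted over the list alone, with Tnfaip6 (3.00), Cd44 (2.63) and Tlr2 (1.59), adjusted p = 0.0154 with an estimated correlation. All 24 mitosis genes rose (Mki67 2.54), also all 24 adjusted over the list alone, and 16 of 23 DNA replication genes, 17 adjusted over the list alone (Cdt1 0.82). Macrophage genes rose in 21 of 22 (Mpeg1 3.91, Itgam 3.83), matrix and collagen genes in 15 of 19 (P4ha3 2.93), chemokine, cytokine and adhesion genes in 22 of 25 (Cxcl2 4.20) and proteases and inhibitors in 19 of 21, with 1 fallen (Mmp12 4.44). Adjusted over the list alone these counts were 21, 15, 23 and 19. With an estimated correlation these 6 lists had adjusted p values from 0.00272 to 0.0276.

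Other lists passed at the preset correlation and not with an estimated one. Contractile genes fell in 19 of 21 (Synpo2 -1.18, Lmod1 -1.04), 20 adjusted over the list alone, adjusted p = 0.216 with an estimated correlation. Neutrophil genes rose in 10 of 15 with 1 fallen, the same numbers adjusted over the list alone (Il1r2 3.96), adjusted p = 0.0641 with an estimated correlation. Interferon response genes rose in 12 of 18, 16 adjusted over the list alone (Oas2 2.10), adjusted p = 0.164 with an estimated correlation. Immediate early genes rose in 9 of 20, 11 adjusted over the list alone (Egr2 2.18), adjusted p = 0.0652 with an estimated correlation. Hypoxia genes rose in 4 of 17, also 4 adjusted over the list alone (Slc2a1 0.91, adjusted p = 0.497 with an estimated correlation), and unfolded protein response genes in 5 of 15, 8 with 1 fallen adjusted over the list alone (Sdf2l1 0.90, adjusted p = 0.0921 with an estimated correlation). The neuron and chromaffin list was lower on average (-1.42) with 0 of 11 members passing, also 0 adjusted over the list alone, adjusted p = 0.675 with an estimated correlation. Without Has3-deficient non-ligated array 3 this list was at -0.65 and did not pass. Adventitial fibroblast genes went both ways, with 4 up (Lum 1.08) and 3 down (Clec3b -0.77) of 13, and the list did not pass.

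Genotype in ligated arteries changed no gene past the threshold. Of 22180 genes tested with limma 0 passed, the lowest adjusted p was 0.368, and 910 had an unadjusted p under 0.05, where 1109 are expected by chance. Has2, Has1 and Has3 did not pass, and neither did the hyaluronan list (mean difference -0.06, adjusted p = 0.216). Mir3108, a microRNA gene, had the lowest p (0.97 ± 0.15, adjusted p = 0.368), followed by genes such as Gucy1a1 (0.53), a subunit of the receptor of nitric oxide, and Dbf4 (-0.45), an activator of DNA replication, which did not pass either. In simulated data with 200 changed genes, 53.7% of changes of 0.5 log2 units and 86.6% of changes of 1 were recovered. The adjusted threshold is stricter where fewer genes change, so these shares overstate what could be found if few genes changed here. Mir3108, at 0.97, did not pass the threshold, and this comparison does not settle whether it differs in ligated arteries.

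Contractile genes were higher on average in Has3-deficient ligated arteries, by 0.28. The difference was positive for 20 of 21 members, of which 0 passed over all genes and 0 adjusted over the list alone; the list had an adjusted p = 4.9e-12 at the preset correlation and an adjusted p = 0.880 with an estimated correlation. Fat genes were higher by 0.75, positive in 15 of 15 with 0 passing and 0 adjusted over the list alone (adjusted p = 3.9e-06, adjusted p = 0.880 with an estimated correlation). Skeletal muscle genes were higher by 0.13, with 0 of 20 passing and 0 adjusted over the list alone (adjusted p = 0.0270, adjusted p = 0.999 with an estimated correlation). The skeletal muscle list did not pass without wildtype array 2 (0.105) or 4 (0.12) or Has3-deficient array 5 (0.12) or 6 (0.096). With fry 0 lists passed.

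Between genotypes 19 genes passed in non-ligated arteries, 2 higher and 17 lower in Has3-deficient ones. An unadjusted p under 0.05 was seen for 2979 genes, where 1109 are expected by chance. Of 35 splits of these arrays 4, the real one included, gave at least 19 genes, so chance cannot be excluded for this count. Both higher genes are small RNA genes, n-R5s136 (1.33 ± 0.20, adjusted p = 0.0385) and Mir3108 (1.07 ± 0.14, adjusted p = 0.0339), and all 17 lower genes changed by less than 2-fold. Among these, Enpp3, an ectonucleotidase, fell by 0.61, Ctbs by 0.55, Cirbp, an RNA-binding protein induced by cold, by 0.52, Gpr137b by 0.47, Rad50, of DNA repair, by 0.44, Mospd2 by 0.44, B4galt1, a galactosyltransferase, by 0.42 and Pqlc3 by 0.40. This count depends on single arrays: without array 2 or 3 of wildtype, or array 2 or 3 of Has3-deficient, non-ligated arteries it is 0, without wildtype arrays 1 and 4 it is 9 and 12, and without Has3-deficient arrays 1 and 4 it is 15 and 280.

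Genes of adventitial fibroblasts were lower on average in Has3-deficient non-ligated arteries. The difference was negative in all 13 members (mean -0.25), with 0 passing over all genes and 9 lower adjusted over the list alone, such as Dpt (-0.45), Lum (-0.42) and Pi16 (-0.38). The list mean was 0.19 ± 0.05 (standard deviation) in wildtype and -0.06 ± 0.03 in Has3-deficient arteries, without overlap; the exact permutation p = 0.0286 is the smallest that 4 against 4 arrays can give. The list had an adjusted p = 3.4e-08 at the preset correlation, an adjusted p = 0.0845 with an estimated correlation and an adjusted p = 0.00384 with fry.

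Other lists passed at the preset correlation alone. Macrophage genes were lower (-0.21; 0 of 22 passed, 1 adjusted over the list alone, Mrc1 -0.70, adjusted p = 0.926 with an estimated correlation), and so was the hyaluronan list (-0.12; 0 of 24 passed and 0 adjusted over the list alone, adjusted p = 0.370 with an estimated correlation). Matrix and collagen genes were higher (0.17; 0 of 19 passed, 2 adjusted over the list alone, Col5a3 0.50 and Col1a1 0.42, adjusted p = 0.770 with an estimated correlation). Lists of other tissues were higher as well: neuron and chromaffin (1.24, adjusted p = 0.857 with an estimated correlation), skeletal muscle (0.17, adjusted p = 0.857 with an estimated correlation), Schwann cell (0.23, adjusted p = 0.770 with an estimated correlation) and epithelium (0.25, adjusted p = 0.370 with an estimated correlation). None of their members passed, and none adjusted over the list alone.

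Leaving out 1 array ended most of these list calls. Macrophage genes did not pass without wildtype array 1 (-0.13) or Has3-deficient array 1 (-0.07), hyaluronan genes without wildtype array 4 (-0.11) or Has3-deficient array 1 (-0.12) or 3 (-0.10), and matrix and collagen genes without Has3-deficient array 1 (0.13). Neuronal genes did not pass without Has3-deficient array 3 (0.47), and skeletal muscle genes without array 4 (0.04). Schwann cell genes did not pass without wildtype array 3 (0.16) or 4 (0.18) or Has3-deficient array 1 (0.22), 3 (0.17) or 4 (0.18). Epithelial genes did not pass without wildtype array 2 (0.23) or 4 (0.25) or Has3-deficient array 1 (0.30) or 4 (0.10). Adventitial fibroblast genes passed with each array left out in turn.

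**Figure D3:**
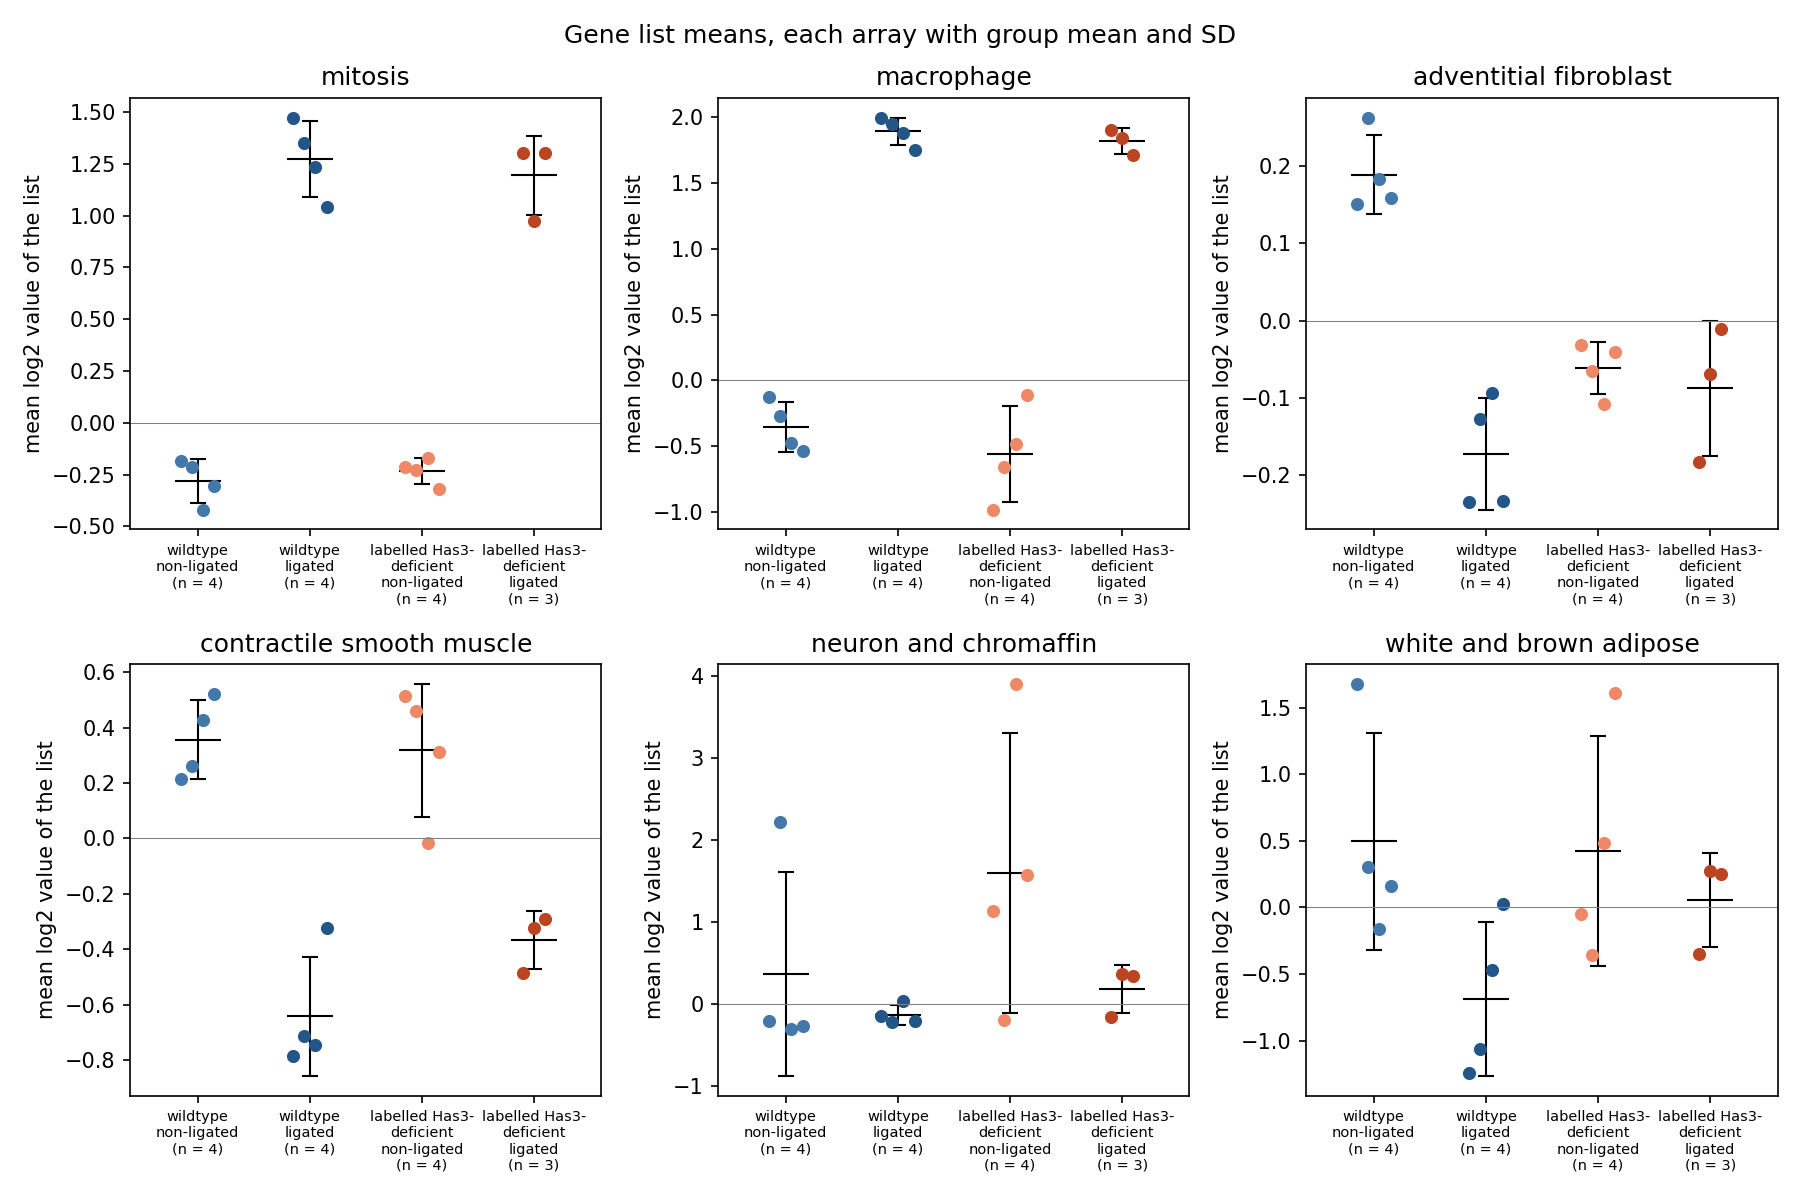
Means of 6 gene lists in each of the 15 arrays, log2 units relative to the median of each gene, with group mean and standard deviation. Mitosis and macrophage genes rose and contractile genes fell with ligation in both genotypes. Single non-ligated arrays stand apart in neuronal genes (3.90 in Has3-deficient array 3) and in fat genes (1.68 in wildtype array 1).

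The ligation response differed between genotypes for no single gene. With limma 0 of 22180 genes passed and the lowest adjusted p was 0.440. An unadjusted p under 0.05 was seen for 1802 genes, where 1109 are expected by chance. Gucy1a1 (0.78), Phf11c (0.59) and Rap2a, a small GTPase (-0.70), were among the genes with the lowest p and did not pass. In simulated data with 200 changed genes, 35.8% of differences of 0.5 log2 units and 76.1% of differences of 1 were recovered. Here too the shares would be lower if few genes differed, since the adjusted threshold is then stricter.

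Adventitial fibroblast genes differed as a list in their ligation response: the list fell in wildtype and did not pass in Has3-deficient arteries. The difference of responses was positive in 13 of 13 members (mean 0.34), with 0 passing over all genes and 5 adjusted over the list alone: Dpt, a matrix protein of the dermis and adventitia, Mfap5, Cd34, Pi16 and Col14a1. The list had an adjusted p = 1.28e-09 at the preset correlation, an adjusted p = 0.0490 with an estimated correlation and an adjusted p = 0.0122 with fry. Much of it lies in the non-ligated arteries, where the list differed by -0.25, against 0.09 in ligated ones (adjusted p = 0.0679). Contractile genes had a smaller mean fall in Has3-deficient arteries (difference 0.315, adjusted p = 0.983 with an estimated correlation). Of 21 members 0 passed, and 0 adjusted over the list alone. For fat genes the difference was 0.82 (adjusted p = 0.986 with an estimated correlation), with 0 of 15 passing and 0 adjusted over the list alone. The fat list did not pass without wildtype non-ligated array 1 (0.43).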

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

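The comparison of ligation responses over the gene lists was planned; the tests of explanations for contractile and neuronal genes were chosen only after these patterns were seen (for the neuronal and chromaffin genes in no list, before their own values were), as were the limit of 1 log2 unit for neuronal and fat list means and the bound set for genotype in the neuronal test.

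Single arrays lay outside the other arrays of their group in 5 of 102 tests of list means and hyaluronan synthases (4.9%, where chance gives about 5%), and in 27 of 462 tests of named genes (5.84%). In wildtype non-ligated array 1 the respiratory chain list stood at 0.96 (others -0.07, 0.05 and 0.08), and in array 2 the neuron and chromaffin list stood at 2.22 (others -0.31, -0.27 and -0.20). In wildtype ligated array 4 contractile genes were less reduced (-0.32; others -0.79, -0.75 and -0.71), and in array 3 interferon response genes stood at 1.10 (others 0.32, 0.32 and 0.34). In Has3-deficient non-ligated array 4 epithelial genes stood at 0.64 (others 0.03, 0.04 and 0.05).

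The ligation response differed between genotypes for 3 lists with camera at the preset correlation: contractile genes by 0.31, adventitial fibroblast genes by 0.34 and fat genes by 0.82. Of these, adventitial fibroblast genes alone also passed with an estimated correlation (adjusted p = 0.0490).

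Contractile genes were higher in Has3-deficient than in wildtype ligated arteries by 0.28, and 4 of the 35 splits of the 7 ligated arrays gave a difference as large, so chance cannot be excluded. A weaker ligation response of the whole artery may contribute but is not shown. After scaling by each array's response over other genes 83.3% of the difference was left (0.23, exact permutation p = 0.143). The response score was 1.03 ± 0.105 (standard deviation) in wildtype against 0.926 ± 0.0942 in Has3-deficient arteries (exact permutation p = 0.2). Fat left on the arteries would dilute contractile genes, so it predicts fewer of their transcripts where fat genes are higher. The fat list instead differed by 0.75 in the same direction as contractile genes, but both differences were known when this was written and it lies within the spread of the arrays (exact permutation p = 0.114), so it excludes nothing. A weaker response, fat and a genotype effect on smooth muscle stay open.

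Neuronal and chromaffin genes were high in non-ligated arrays: list means of 3.90 in Has3-deficient array 3, 1.57 in array 4 and 1.13 in array 1, and 2.22 in wildtype array 2. Ganglion or chromaffin tissue is a candidate source in Has3-deficient array 3: of 19 neuronal and chromaffin genes in no list 17 lay over 1 log2 unit above their median there (2.73% of all genes did), such as Syt1 at 5.98 and Chrna3 at 5.76, and of the list's own genes Dbh stood at 6.90. The same count was 11 in wildtype array 2, 8 in Has3-deficient array 4 and 4 in array 1, where Dbh stood at 0.35 beside Th at 2.69 and Snap25 at 2.72, so the source stays open for array 1. Genotype as the sole cause is argued against by wildtype array 2, which lay above the median of the Has3-deficient non-ligated arrays. The non-ligated groups differed by 1.24 with a pooled standard deviation of 1.49 (exact permutation p = 0.286). Ligated arteries were not in this test. Their list means were 0.365 and 0.343 in Has3-deficient arrays 5 and 6 (Dbh at 1.76 and 1.73) and -0.156 in array 3 (Dbh at -0.21). In wildtype ligated arrays list means ran from -0.221 to 0.036, with Dbh at 0 or lower. In every ligated array 0 of the 19 genes in no list lay over 1 log2 unit. Per the labels adherent wound tissue was removed, and a contribution of genotype or of innervation stays open.

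Probe sets without a single gene name also responded to ligation: with limma 1240 of 10272 passed in wildtype and 629 in Has3-deficient arteries. They are not described as genes here.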

How the results depend on the processing

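Counts of genes changed by ligation stayed between 5381 and 6773 in wildtype and between 2785 and 4946 in Has3-deficient arteries in the alternatives run, except among bright genes. The count by genotype in non-ligated arteries ran from 0 to 280. Planned and not run, since levels are lost: the brightest probe set, the filter on dim genes and the variance trend. Quantile normalization ran on centred values. Unless stated, the cause was not tested.

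With arrays left out in turn, genes changed by ligation were 5381 to 5698 in wildtype and 2785 to 4354 in Has3-deficient arteries; by genotype 0 to 0 in ligated and 0 to 280 in non-ligated arteries; by interaction 0 to 0. Lists passing were 17 to 19, 14 to 19, 2 to 8, 3 to 11 and 3 to 8, in the same order.

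For genotype in non-ligated arteries the 19 genes became 9 with array weights and 0 with only the 2 groups compared. With a fixed replicate block they became 0 (wildtype ligation 6098). For genotype this block joins arrays of different genotypes by number, which cannot be 1 animal, so that 0 says nothing about stability. The 19 genes became 18, all among the 19, with the replicate block as a random effect within genotype, and 83, holding 4 of the 19, among 1951 bright genes. Without the array highest in neuronal genes they became 0; without the arrays high in neuronal genes 163, holding 4 of the 19, in a fit with 3 of the 4 Has3-deficient and 1 of the 4 wildtype non-ligated arrays removed, so that other groups supply the spread and neither this count nor others from this setting show stability; without the arrays high in fat genes 116, holding 16; with neuronal and fat list means as covariates 219, holding all 19. In ligated arteries 1 gene, Mir3108, passed with array weights, and 1, again Mir3108, with only the 2 groups compared. Bright genes only gave 708 and 412 of 1951 for ligation in wildtype and Has3-deficient arteries.

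In the order used above, an estimated correlation left 4, 7, 0, 0 and 1 lists; fry left 0, 1 and 1 in the last 3 comparisons. Exact permutation of list means left 0 in each of the first 4: the smallest p, 0.0286, was reached by 16, 11, 0 and 2 lists where 18 are needed, so this test could pass a list only together with many others; the lowest adjusted p values were 0.0554, 0.0806, 0.633 and 0.442. Among bright genes 5 lists could be tested and 1, 1, 1, 0 and 1 passed. Quantile normalization applied again left 5 lists for genotype in non-ligated arteries and 1 for the interaction. Interaction lists became 5 without the array highest in neuronal genes, 10 without the arrays high in neuronal genes (again with 1 Has3-deficient non-ligated array), 7 without the arrays high in fat genes and 6 with the covariates. The interaction of adventitial fibroblast genes passed in all 23 alternatives run for it, with the highest adjusted p, 0.0490, from the estimated correlation. These overlap: leaving out Has3-deficient non-ligated array 3 and leaving out the array highest in neuronal genes are 1 fit. Also counted is the setting with 1 Has3-deficient non-ligated array, which shows no stability. Except for the estimated correlation and fry, all use the preset correlation, and exact permutation was not run for the interaction.

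The direction given by camera reversed for these lists; the list mean changed sign too, except for cholesterol synthesis in the interaction (0.01 with all arrays) and neuron and chromaffin genes for genotype in non-ligated arteries (1.24 with all arrays), whose means kept their sign or became 0. Without wildtype non-ligated replicate 1, the respiratory chain list for genotype in non-ligated arteries was 0.19. Without Has3-deficient non-ligated replicate 3, which is the array highest in neuronal genes, cholesterol synthesis was -0.25 for genotype in non-ligated arteries and 0.31 in the interaction; with each array left out in turn these ran from -0.248 to 0.251 and from -0.185 to 0.314. Without the arrays high in neuronal genes, neuron and chromaffin genes were 0.38 for ligation in Has3-deficient arteries and 0.064 for genotype in non-ligated arteries, cholesterol synthesis -0.44 in non-ligated arteries and 0.50 in the interaction, and Schwann cell genes -0.059 in non-ligated arteries. With neuronal and fat list means as covariates, the respiratory chain was 0.17 (0.165) for ligation in wildtype, -0.23 for genotype in ligated arteries and -0.24 in the interaction; cholesterol synthesis was -0.28 and neuron and chromaffin 0 for genotype in non-ligated arteries, the last by construction.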

Other observations

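The ligation comparisons and the counts over splits of the arrays were planned before the values were seen; the tests of Mir3108 were chosen only after its result was seen (that of its host gene before the host gene's value was), as were the average over artery states, the window of 100 genes and the bound set for the wider group.

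Some genes of the growth factor, clock, mast cell and platelet lists responded to ligation in both genotypes. Hgf, a growth factor of mesenchymal cells, rose by 1.81 in wildtype and 1.72 in Has3-deficient arteries. In wildtype Pdgfb rose by 1.27 and Pdgfd fell by 1.48. The clock gene Cry2 fell by 0.81 in wildtype and by 0.96 in Has3-deficient arteries, though in wildtype it did not pass with quantile normalization applied again, and Nr1d1 fell by 1.05 in wildtype. Hdc, of the mast cell list (4.41 and 3.99), rose in both, as did the chemokine Pf4, of the platelet list (2.28 and 2.39). Neither list passed in either genotype, so these are changes of single genes and do not show more mast cells or platelets.

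Mir3108 was higher in arrays labelled Has3-deficient in both artery states, by 1.02 ± 0.10 on average (2.03-fold, adjusted p = 0.00263), and was the 1 gene that passed in this average with limma (1886 at an unadjusted p under 0.05). DNA flanking Has3 carried over with the targeted allele is a candidate explanation. Mir3108 lies on chromosome 8 as Has3 does, and 0.379% of 22139 genes with a position lie as near. The list of neighbours of Has3 (22 measured), fixed before the data were examined to mark such carry-over, did not pass for genotype in either artery state. That list test seeks a shared direction, so it does not exclude carry-over. More transcript of its host gene Zfhx3 is argued against, since Zfhx3 differed by 0.11 ± 0.09. A wider group of changed genes around Has3 stays open: 10 of the 100 nearest genes had an unadjusted p under 0.05 against 8.5% of 22038 others (Fisher's exact p = 0.588, odds ratio 1.2, interval 0.553 to 2.31). An effect of the missing Has3 gene on Mir3108 was not tested.

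Other splits of the same arrays were counted for each gene count. For ligation in wildtype 1 of 35 splits, the real one, gave as many as 6173 genes (highest other 1). In Has3-deficient arteries 1 of 35 gave as many as 4055. This is the lowest share that 35 splits can give, so chance is argued against for both but not excluded. The highest other split in Has3-deficient arteries called 2115 genes. It differs from the real split in placing Has3-deficient non-ligated array 3, the one highest in neuronal genes, with the ligated arrays. For genotype in ligated arteries the real count is 0 and the highest other split gave 1, and for the interaction the real count is 0 and the highest other gave 5. Every split, 35 of 35 and 100 of 100 drawn, reaches a count of 0, so these counts say nothing about chance. For genotype in non-ligated arteries 4 of 35 splits gave at least the real 19, so chance cannot be excluded for this count. The highest other split, with 354 genes, sets wildtype arrays 1 and 2 with Has3-deficient arrays 3 and 4 against the rest; so many calls point to a structure of the samples other than genotype, and these arrays include those highest in neuronal and fat genes.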
